A study of Drosophila melanogaster with 3 samples.

How the data were processed

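Small RNAs were measured in ovaries of 3 transgenic strains (H90, H95 and H111), with 1 library per strain. Per the labels' protocols, total RNA was isolated with Trizol, the 19 to 29 nt fraction was taken from a polyacrylamide gel, and the libraries were sequenced on an Illumina instrument. The deposited files give the count of raw reads for each distinct sequence, with no header, no alignment and no gene name. The submitters' processing notes name Bowtie and the genome build dm3 without saying what they were used for. Adapter removal and length filters are not stated. The files hold sequences of 18 nt and longer, up to 47 nt in H90 and H111 and up to 121 nt in H95.

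A genome sequence was not used here, only the BDGP6 gene annotation, so reads were not mapped to the genome. Contigs were built from reads of 23 to 29 nt of all 3 libraries pooled, by greedy extension over k-mers of 19 nt, taking the most frequent next base. k-mers needed at least 3 counts in contigs grown from primers. Other contigs needed 5 counts, a starting k-mer with at least 30 and a length of at least 300 nt. A contig was named after a transposon family when both primers of a pair lay in it with at most 1 mismatch each and at most 500 nt apart. Of 49 primer pairs tried, 17 were found, and they named 16 contigs: HeT-A, TART, roo, blood, gypsy, copia, diver, 412, 297, jockey, Max-element, I-element, accord, invader1, 1731 and the cluster 42AB. A pair that was not found says nothing about its family. TAHRE, flamenco and the other listed families were not analysed here for that reason. The primers, the 90 listed miRNAs, lacZ, EGFP, 2S rRNA, the P-element end, esi-2.1 and Su(Ste)-4 are sequences written from general knowledge, not taken from a reference file, so the names rest on that knowledge. As a check of strand, which says nothing of the family, the longest frame without a stop codon lay on the forward-primer strand in 16 of 16 named contigs. The margin was small for the I-element, at 207 against 177 nt. That strand is called sense. Greedy contigs can join copies of a family or different families, so only reads within 1000 nt of the primer pair were counted for a named contig. The primer pairs, the k-mer settings, the naming rule and that distance were chosen after the files were seen, and the contigs come from the same libraries that they compare.

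Reads were matched to contigs without mismatch, and a read with several places was divided over them. For 42AB only reads with 1 place among the contigs were counted. Places were counted among contigs, not in the genome, so these settings do not measure how often a read occurs in the genome. piRNA size was 24 to 29 nt. Levels are rpm (reads per 1000000 reads of the file), and the log2 ratio of 2 libraries was taken after adding a pseudocount of 1 rpm. A set of 471 piRNA-like contigs, named and unnamed, had at least 1000 reads over the 3 libraries and at least 50% of reads with U at position 1. The median log2 ratio of those with at least 1000 reads over both libraries of a pair was subtracted for values relative to the median. Counting intervals apply to the ratio without a pseudocount. For values relative to the median they take the median as fixed. miRNAs were counted by reads of 20 to 24 nt that begin with the first 20 nt of the mature sequence, in miRNA rpm (reads per 1000000 miRNA reads). Some listed miRNAs had no reads, which can also mean that the remembered sequence is wrong. TMM factors from edgeR 4.0.16 in R 4.3.3 served as an alternative scaling only. Ping-pong pairs were counted as the sum over positions of the product of sense and antisense reads at each overlap of 1 to 20 nt of the 5′ ends. Gel size markers were recognised by an 8-nt site and 2 abundant sequences of 19 and 30 nt.

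With 1 library per strain no test was made and no p-value is given. The 3 pairs of strains were compared by values and exact intervals at the 95% level that cover counting error only. The detection floor of 3 reads was 0.149 rpm in H90, 0.151 rpm in H95 and 0.186 rpm in H111. Lists fixed before the data were examined were described by the percentile of their median among 10000 random lists, each member replaced by 1 of the 20 contigs or miRNAs nearest in mean level. The ovary, testis and let-7 cluster lists hold miRNAs that share a locus and are described by their median alone. These lists were the telomeric, germline and follicle cell families and the ovary, let-7 cluster, muscle, neuron, gut and fat body, and testis miRNAs. Only members with a named contig or a listed miRNA entered a list. Of the 14 testis miRNAs planned, 13 were listed. By a rule fixed at the same time, the items to name or summarise were the members of those lists, the 10 families and 10 miRNAs with the largest absolute log2 ratio in each pair with at least 1000 or 100 reads, and the highest 10. The telomeric ones are given in full and the rest summarised. Strain and library cannot be told apart.

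The counting functions were tested on simulated data: Poisson counts for 475 contigs at the observed depths, with 200 contigs changed. For H95 against H90, 100 of 100 contigs changed 4-fold were found at least 2-fold apart, 0 of 275 unchanged contigs were, and 95.8% of intervals held the true value. For H111 against H90 and H95 against H111 the contigs found were the same in number and 93.9% and 94.9% of intervals held it. Random 5′ ends gave 5.21% of pairs at 10 nt. Alternatives covered the scaling, the size range, distinct sequences, 1 mismatch, the number of places, minimum counts, the pseudocount and thinning to 16098050 reads. The scaling to the median contig, totals without markers, and the whole contig or 250 nt around the primers were chosen after seeing the data. Vector parts other than lacZ and EGFP, genic piRNA sources, and rRNA, tRNA and snRNA classes other than 2S rRNA were not analysed here. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.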

Results

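Ovarian small RNAs of 3 transgenic fly strains, H90, H95 and H111, were sequenced. Each strain gave 1 library from a gel fraction of 19 to 29 nt, so no difference below has a replicate check and no test between strains was made. The labels call the strains transgenic and name no construct. The files held 20115167 reads for H90, 19825694 for H95 and 16098050 for H111. The reads fell on 4568429, 5010240 and 2662085 distinct sequences. All intervals are exact 95% intervals (Clopper-Pearson for shares and for ratios of counts, Poisson for single counts) and cover counting error only, since copies made by PCR are not independent molecules. No genome sequence was at hand, so transposon families were read from contigs built of the small RNAs themselves and named by primer sequences written from general knowledge. miRNAs, 2S rRNA and lacZ were likewise recognised by sequences from general knowledge.

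The libraries differed first in the balance between piRNAs, the 24-29 nt class that silences transposons in the germline, and the shorter miRNAs and siRNAs. Reads of 24-29 nt made up 48.7% of H90 (48.7 to 48.7), 55.5% of H95 (55.5 to 55.5) and 30.3% of H111 (30.3 to 30.3). Reads of 21-23 nt made up 39.6%, 27.5% and 36.6%. The upper end of the size range differed too. Reads of 28 nt were 2.27% of H90, 5.91% of H95 and 0.880% of H111, and reads of 29 nt were 0.308%, 2.92% and 0.234%. The 24-29 nt share and levels in rpm may thus also reflect the sizes recovered from the gel, which cannot be told apart from the strain. The listed miRNAs took 22.6% of the reads in H90, 13.3% in H95 and 19.8% in H111, and 2S rRNA, a small ribosomal RNA of flies, took 1.12%, 1.33% and 1.59%. Reads with an 8-nt restriction site that is often built into gel size markers made up 2.43% of H90, 5.59% of H95 and 19.98% of H111. Those that matched 1 of 2 abundant marker sequences made up 1.997%, 4.83% and 17.4%. The matched marker sequence was the 19-mer in H90 and H111 and mostly the 30-mer in H95. Each library also held other 30-nt reads with the site. Without reads with the site, the 30-nt reads outside the marker, miRNA, 2S rRNA and esi-2.1 classes fell from 56095 to 30563 in H90. They fell from 207532 to 145450 in H95 and from 83893 to 23797 in H111. Reads in H95 reached 121 nt, against 47 nt in H90 and H111. Without the reads that matched a marker sequence the 24-29 nt share of H111 was 36.7%, and without all reads with the site it was 37.7%. With each distinct sequence counted once it was 68.2% in H90, 69.3% in H95 and 61.9% in H111. Of the 49192 sequences of H111 with at least 10 reads, 76.0% also had them in H90 and 54.4% in H95. H90 and H95 shared 49639 such sequences, 44.2% of the 112292 of H90, and H90 and H111 shared 37394. The 44.2% has another base than the 76.0%, so these 2 shares cannot be set against each other.

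**Figure D1:**
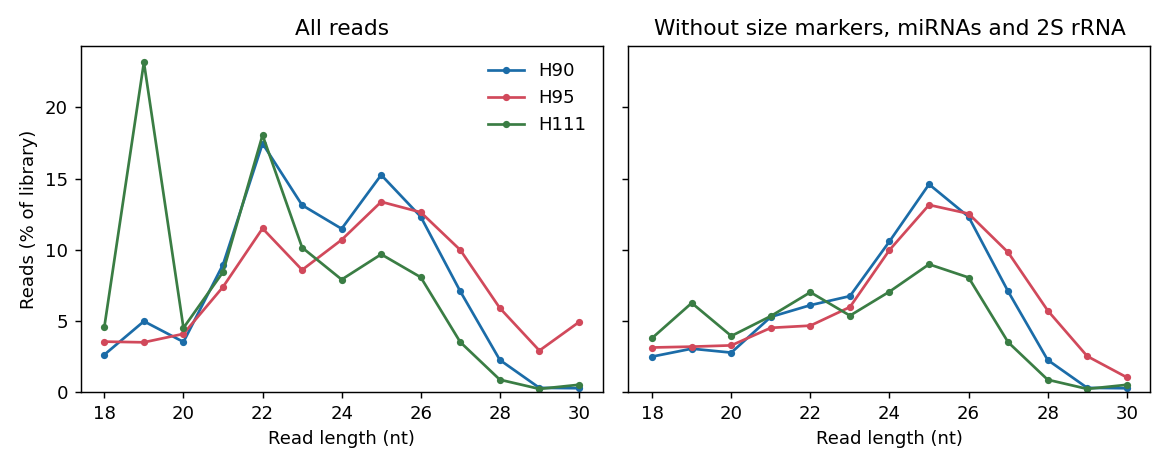
Share of reads (%) at each read length (nt) in the 3 libraries, 1 line per strain, with all reads on the left and without size markers, miRNAs and 2S rRNA on the right. The piRNA-size class had its most frequent length at 25 nt in each library, and the peak at 19 nt in H111 falls from 23.2% to 6.27% without these classes, still above 18 and 20 nt.

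HeT-A and TART are the retrotransposons that maintain fly telomeres, and the series is about piRNAs from HeT-A, so the first comparison asks how many of these small RNAs each strain had and from which strand. HeT-A small RNAs of 24-29 nt came from both strands in all 3 libraries, at 1049.85 rpm (reads per 1000000 reads of the file) in H90 (1036 to 1064), 1284 rpm in H95 (1269 to 1300.2) and 653 rpm in H111 (640.2 to 665). The antisense strand gave 55.5% of them in H90 (54.8 to 56.2), 57.2% in H95 (56.5 to 57.8) and 52.6% in H111 (51.6 to 53.5). TART gave 757 rpm in H90 (745 to 769), 1570.1 rpm in H95 (1553 to 1588) and 383 rpm in H111 (374 to 393), with 72.9%, 67.1% and 54.6% antisense. The matched parts lie within 1000 nt of the primer pair on contigs of 3546 nt for HeT-A and 5790.0 nt for TART.

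Which strain had more HeT-A small RNA depended on the scale. Against H90, the HeT-A log2 ratio in rpm was 0.29 in H95 (0.26 to 0.32) and -0.69 in H111 (-0.72 to -0.65). The median of all piRNA-like contigs was itself shifted by 0.33 in H95 and by -1.20 in H111, and by 1.46 between H95 and H111. Of 24-29 nt reads outside the miRNA, 2S rRNA, esi-2.1 and marker classes, contigs held 33.0% in H90, 36.3% in H95 and 28.2% in H111. Values relative to the median therefore also depend on how much of each library the contigs captured. Relative to that median, HeT-A stood at -0.043 in H95 (-0.069 to -0.016), at 0.51 in H111 (0.48 to 0.55), and at -0.49 for H95 against H111. These intervals take the median as fixed and leave out its own error. HeT-A was level with the median in H95 against H90, at percentile 47.3 of the contigs. For H111 against H90 and H95 against H111 the direction was reversed. TART relative to the median was at 0.72 in H95 (0.69 to 0.75) and 0.22 in H111 (0.18 to 0.26) against H90. In rpm the H111 value of TART was -0.98, the reverse direction, and that of H95 was 1.05. The BDGP6 annotation lists 27 HeT-A insertions, of which 15 are on chromosome 4, 10 on X, 1 on 2R and 1 on 3L, and it lists TART on 4, X, 3L, 3R and 2R. The reads were not assigned to single insertions.

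**Figure D2:**
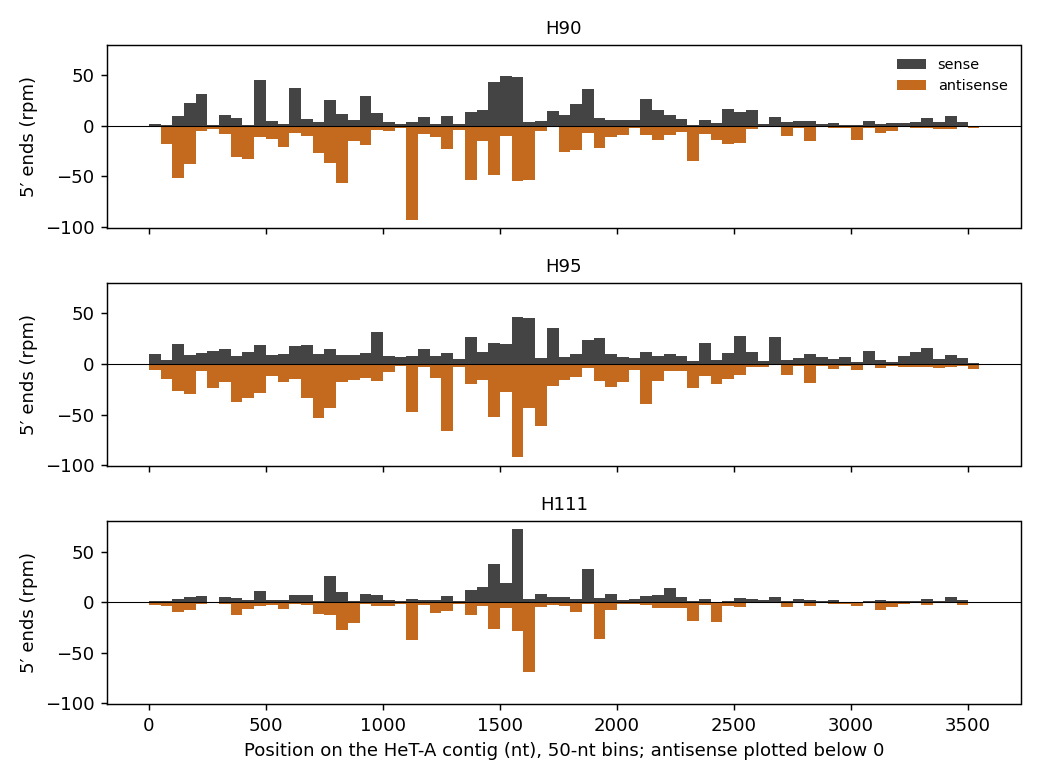
5′ ends of 24-29 nt reads (rpm) in bins of 50 nt along the HeT-A contig (position in nt), 1 panel per strain, with the sense strand above 0 and the antisense strand below. Both strands have reads along the contig in H90, H95 and H111, and the antisense share lies between 52.6% and 57.2% in the part near the primer pair.

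HeT-A small RNAs were examined for the marks of ping-pong amplification, in which sense and antisense piRNAs cut each other's precursors and overlap by 10 nt at their 5′ ends. The overlap of 10 nt held 62.6% of HeT-A pairs at overlaps of 1 to 20 nt in H90, 60.9% in H95 and 64.7% in H111, and 51.0%, 47.1% and 43.0% of the pairs on all 471 piRNA-like contigs. Antisense HeT-A reads began with U in 83.8%, 82.7% and 71.0% of cases, and sense HeT-A reads in 54.4%, 60.2% and 61.2%. Sense HeT-A reads had A at position 10 in 57.4%, 60.1% and 56.9%. TART had 32.9% of pairs at 10 nt in H90, 48.7% in H95 and 14.1% in H111. The HeT-A share rests on abundant sequences and on place: with each distinct sequence counted once it was 6.90%, 7.43% and 8.10%, and within 250 nt of the primer pair it was 29.9%, 49.4% and 13.6%. Among all 24-29 nt reads outside the miRNA, 2S rRNA, esi-2.1 and marker classes, U at position 1 was found in 74.1% in H90, 70.2% in H95 and 63.5% in H111, and A at position 10 in 31.2%, 32.9% and 32.1%. Reads of tRNA, snRNA, other rRNA and other siRNAs were not removed, so these shares are not of piRNAs alone.

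The next comparison asks whether other transposon families differed between the strains in the same way. Relative to the median contig, jockey, a germline non-LTR element, was higher in H95 than in H90 at 0.71 (0.68 to 0.75), and blood, an LTR retrotransposon, was lower at -0.97 (-1.005 to -0.93). The element accord was at -0.62 and roo at -0.28. Of the 15 named families, 3 lay above the median and 12 below it for H95 against H90, and none was 2-fold off. For H111 against H90, 8 lay above and 7 below. In that pair 1 LTR family of the germline list stood at 1.66, the value at the right edge of the plot of family ratios, with 891 rpm in H111 and 649 rpm in H90. The elements invader1 and diver followed at 0.78 and 0.74, and accord was lowest at -0.66. For H95 against H111, 7 lay above and 8 below, with jockey at 0.59, invader1 at -1.14 and the LTR family just named at -1.84. In rpm, without the median shift, 12 of the 15 families were higher in H95 than in H90 and 14 were lower in H111 than in H90. When only reads with 1 place among the contigs were counted, roo was at 0.61 for H95 against H90.

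The fixed family lists were set against 10000 random lists of contigs of like level. The telomeric list (HeT-A and TART) had a median of 0.34 for H95 against H90, at percentile 99.2, with 1 of its 2 members above the contig median and 1 below. Neither member was extreme by itself, with TART at percentile 83.4 and HeT-A at 47.3 of all contigs, and jockey at 83.0 and the 42AB contig at 83.7 stood level with TART. It lay at percentile 81.8 for H111 against H90 and 73.8 for H95 against H111. The 8 germline families had medians of -0.21, 0.24 and -0.49 in the same order, at percentiles 19.9, 65.2 and 5.11. The 3 families of the follicle cell list, among them gypsy, had medians of -0.14, -0.35 and 0.12, at percentiles 50.5, 10.7 and 84.8. Of all piRNA-like contigs, 73 of 471 were at least 2-fold off the median for H95 against H90 (52 higher and 21 lower), 59 of 431 for H111 against H90 (40 higher and 19 lower) and 84 of 464 for H95 against H111 (48 higher and 36 lower). Among contigs with at least 10000 reads these counts were 15 of 159, 12 of 98 and 21 of 125.

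**Figure D3:**
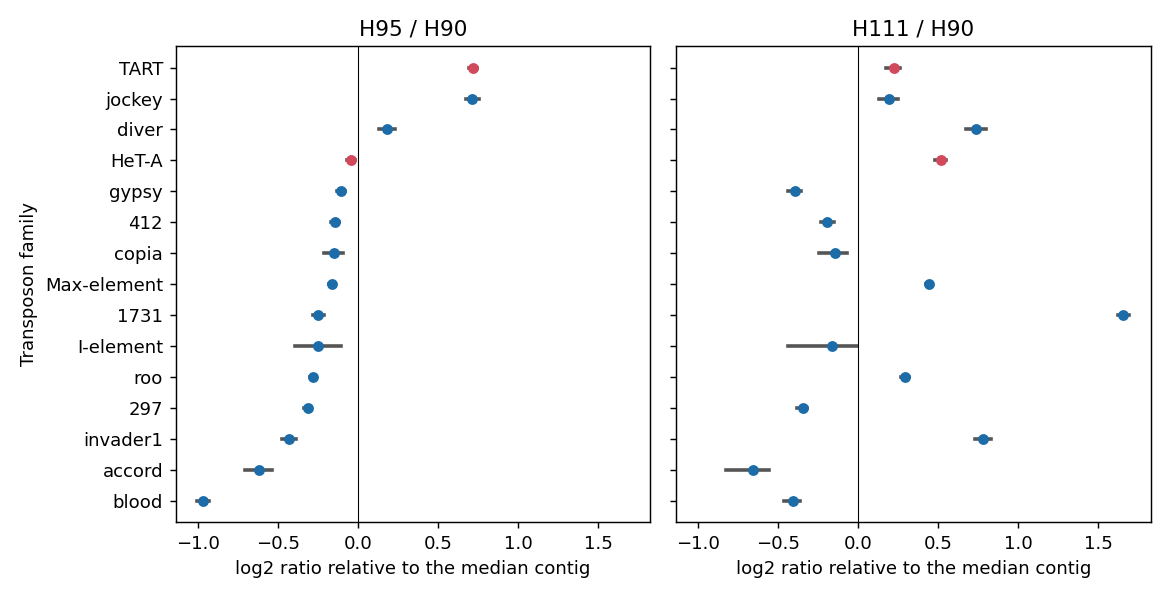
Log2 ratio of 24-29 nt reads relative to the median piRNA-like contig for 15 transposon families, H95 over H90 on the left and H111 over H90 on the right, with 95% counting intervals as bars and telomeric families in red. HeT-A lies at -0.043, level with the median contig, where its rpm ratio is 0.29. In H111 over H90 it lies at 0.51, opposite in sign to its rpm ratio of -0.69. TART lies at 0.72 and 0.22, the latter opposite in sign to its rpm ratio of -0.98.

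The contig named after a primer pair for 42AB, a dual-strand piRNA cluster of the germline, had 275 rpm in H90 (268 to 282), 571 rpm in H95 (561 to 582) and 421 rpm in H111 (411 to 431), counting reads with 1 place among the contigs. The log2 ratio against H90 was 1.05 in H95 (1.01 to 1.10) and 0.61 in H111 (0.56 to 0.67), and it was 0.71 and 1.81 relative to the median contig. H95 against H111 was at 0.44 in rpm and at -1.02 relative to the median, so that direction depended on the scale. In the BDGP6 annotation the cluster lies between the genes Pld and jing, on chromosome 2R from 6255267 to 6502005. Whether the contig, which is 5995 nt long and has an open reading frame of 3054 nt, lies there was not tested, and reads were counted within 1000 nt of the primer pair.

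miRNAs, which do not depend on the piRNA pathway, were compared as a separate class. In H95, miR-958 stood at 584 miRNA rpm (reads per 1000000 miRNA reads) (555 to 614), against 0.659 in H90 (0.136 to 1.93, from 3 reads), a log2 ratio of 8.46 with an interval from 8.24 to 12.1. Its gene mir-958 is annotated at 22669289 to 22669380 on 3L. The let-7 cluster miRNAs miR-100 and miR-125, miR-79 and miR-282 were also higher in H95. miR-79 stood at 2452 miRNA rpm in H95 and 80.4 in H90, and miR-282 at 67324 and 4954. Lower in H95 were bantam, a growth-promoting miRNA, at 61914 against 164009 miRNA rpm, and miR-1, the muscle miRNA, at 5379 against 24260.4. H111 resembled H90 more closely. In H111, miR-92b was higher at 91504 against 22881 miRNA rpm, miR-184 at 194499 against 105701, and miR-8 was lower at 15455 against 49819.

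Among miRNAs with at least 100 reads in the pair, 39 of 73 were 2-fold apart between H95 and H90 (30 higher and 9 lower in H95). The numbers were 16 of 69 between H111 and H90 (5 higher and 11 lower in H111) and 43 of 67 between H95 and H111 (34 higher and 9 lower in H95). These splits depend on the scaling, since the median miRNA was shifted by 0.53, -0.41 and 1.17. With TMM scaling they were 24 higher and 17 lower, 11 and 6, and 22 and 21. In rpm of the whole file they were 20 and 18, 1 and 19, and 25 and 16. Relative to the median miRNA, the log2 ratio H95 over H90 was 7.94 for miR-958, 4.39 for miR-79, 4.17 for miR-308, 4.01 for miR-932, 3.24 for both miR-313 and miR-282, 2.66 for miR-998 and 2.57 for miR-13b. It was -2.70 for miR-1, -1.93 for bantam, -1.68 for miR-318 and -0.72 for miR-989. For H111 over H90 it was 2.41 for miR-92b, 1.29 for miR-184, -1.28 for miR-8, -1.26 for miR-279 and -1.43 for miR-304. The lowest values in H111 were those of miR-961 at -2.12 and miR-963 at -1.92, from 24 and 16 reads in H111 against 220 and 134 in H90. The neighbouring miR-964 and miR-960 stood at -1.26 and -0.81, miR-14 at -0.82 and miR-315 at 1.53. In H95 miR-980 and miR-314 stood at 2.38 and 2.37. The other abundant miRNAs were miR-9c, miR-12 and miR-305, with means of 39760, 38025 and 36340 miRNA rpm over the 3 libraries. Across miRNAs, which are not independent replicates, the levels correlated with r = 0.892 between H95 and H90, 0.979 between H111 and H90 and 0.846 between H95 and H111.

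**Figure D4:**
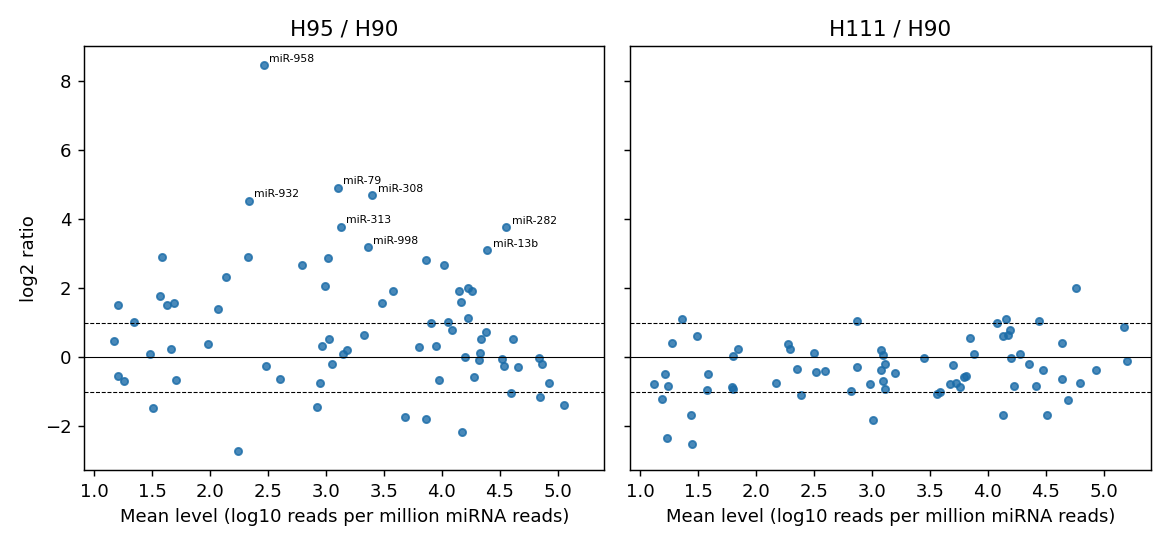
Log2 ratio of miRNAs with at least 100 reads in the pair against their mean level (log10 miRNA rpm), H95 over H90 on the left and H111 over H90 on the right, with dashed lines at 2-fold and names beyond 8-fold. In H95 39 of 73 miRNAs lie on or beyond the lines, and in H111 16 of 69.

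The 13 ovary miRNAs of the fixed list together took 578773 miRNA rpm in H90, 401840 in H95 and 551298 in H111. Their median log2 ratio was -0.061 for H95 over H90 and -0.48 for H111 over H90. Of the 13, miR-310 to miR-313 share a locus, and so do miR-318 and miR-994. The 3 miRNAs of the let-7 cluster had a median of 2.68 in H95, with let-7 itself at 0.28 in miRNA rpm and at -0.49 in rpm of the whole file. Their median in H111 was 0.37. The testis list held 13 miRNAs, of which 6 had at least 100 reads in the pair, miR-959 to miR-964, at a single locus on 2L between 5640940 and 5642201. Its median was -0.24 in H95 and -1.45 in H111, and no percentile is given for the ovary, let-7 cluster and testis lists because random lists of unlinked miRNAs are no match for linked ones. All its miRNAs together took 186, 189 and 61.3 miRNA rpm in H90, H95 and H111. Gut and fat body miRNAs (miR-14 and miR-263a) had medians of 0.15 and -0.12, at percentiles 39.8 and 46.4. Of the muscle list, miR-1 stood at -2.17 and -0.19, and miR-133 had 14 reads in H90, 7 in H95 and 13 in H111. The neuronal miR-124 had 1, 4 and 0 reads. The sequence of the Su(Ste)-4 piRNA, a testis piRNA, had 2, 0 and 1 reads.

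Parts of common fly vectors were searched because the strains are transgenic. lacZ, the bacterial reporter gene, had 75 exact reads of 18-30 nt in H90, 66 in H95 and 28 in H111, spread along most of its 3075 nt. At 24-29 nt this was 2.78 rpm in H90 (2.103 to 3.62), 2.67 rpm in H95 (2.002 to 3.50) and 1.30 rpm in H111 (0.808 to 1.99). The antisense share of the 18-30 nt reads was 37.3% in H90 (26.4 to 49.3), 6.06% in H95 (1.68 to 14.8) and 28.6% in H111 (13.2 to 48.7). EGFP, a sequence from another organism searched in the same way, had 0 reads in each library, and the 3 reads that a count of 0 allows correspond to 0.149 rpm in H90, 0.151 in H95 and 0.186 in H111, where the exact Poisson intervals end at 0.183, 0.186 and 0.229 rpm.

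Endogenous siRNAs are 21-nt RNAs from hairpins and transposons. The hairpin siRNA esi-2.1 had 21.9 rpm at 21 nt in H90 (19.88 to 24.02), 48.5 rpm in H95 (45.5 to 51.7) and 14.2 rpm in H111 (12.4 to 16.1). At 20-22 nt the values were 152, 424 and 89.4 rpm, with the same order of the strains. Most reads of esi-2.1 had other lengths than 21 nt. Those of 21 nt were 440 of 3139 in H90, 962 of 8651 in H95 and 228 of 1460 in H111. HeT-A gave 72.7, 112 and 51.8 rpm at 21 nt. Whether 21-nt reads on HeT-A or other contigs are siRNAs was not tested. Of the 20-22 nt reads on contigs, those of 21 nt were 170825 of 415068 in H90, 157590 of 417793 in H95 and 86028 of 216018 in H111. Over all contigs, the 21-nt reads came to 5.46% of the number of 24-29 nt reads in H90, 4.08% in H95 and 6.60% in H111, and 63.3%, 57.6% and 59.0% of them began with U.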

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

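Signals outside the comparisons were noted where they exceeded the 3 reads that a count of 0 allows. A 19-nt sequence with the restriction site of gel size markers had 379016 reads in H90, 31016 in H95 and 2703799 in H111. A 30-nt sequence with the same site had 709211 reads in H95 and 0 in H90 and H111. Reads over 30 nt, longer than the stated gel fraction, numbered 62907 in H90, 184448 in H95 and 43292 in H111. The first 257 nt of the P-element, the end carried by most fly vectors, had 65 reads of 18-30 nt in H95 and 4 in H111, against 1 in H90. In H95, 64 of the 65 were sense, and the 65 came from 10 distinct sequences. Of the 65, 14 were 21 nt long, from 2 sequences that did not begin with U. Only 1 read, the antisense one, was of piRNA size (24-29 nt).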

How the results depend on the processing

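The alternatives relative to the median contig, without marker reads or all reads with the marker site, per 24-29 nt read, and on the whole contig or within 250 nt of the primers were chosen after seeing the data. So were the choice of miRNAs tested by name, 42AB relative to the median contig, and the use of values relative to the median as the main value for the 13 families other than HeT-A and TART. Of 813 recomputed values, 423 stayed within the counting interval (or within 1.5 times for a count), 366 moved outside it in the same direction or without one, and 24 changed sign. The cause was not tested for any of these changes unless the sentence says so. Counts of miRNAs 2-fold apart stayed within 1.5 times under all alternatives run. No paired analysis was possible because each strain has 1 library. Not run were removal of rRNA, tRNA and snRNA other than 2S, 1 mismatch for base composition, class shares and unnamed contigs, and reads unique in the genome. Reads with 1 place, or counted whole, left HeT-A within its interval, but places were counted among contigs, so this says nothing of copies in the genome. Intervals for the ping-pong share treat it as a share of HeT-A reads, which is an approximation.

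With each distinct sequence counted once, the 24-29 nt share was 68.2% in H90, 69.3% in H95 and 61.9% in H111, and the miRNA share 0.0440%, 0.0419% and 0.0618%. The share with U at position 1 was 64.4%, 61.9% and 57.9%, and with A at position 10 it was 30.3%, 31.9% and 29.5%. The HeT-A ping-pong share was 6.90%, 7.43% and 8.10%. The HeT-A log2 ratio was 0.42 for H95/H90, 0.25 for H95/H111 and, with reversed direction, 0.18 for H111/H90, and that of TART for H111/H90 was also reversed at 0.24. lacZ had 10.7, 10.6 and 7.51 per 1000000 distinct sequences and esi-2.1 had 0.438, 0.798 and 0.376, on another scale than reads.

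Without 2S rRNA the 24-29 nt share was 48.4%, 55.8% and 29.9% in H90, H95 and H111, and without reads that matched a marker sequence 49.7%, 57.6% and 36.7%. Without all reads with the marker site it was 49.9%, 57.6% and 37.7%, the share with U at position 1 was 74.2%, 70.7% and 63.7%, and with A at position 10 it was 31.2%, 32.98% and 31.9%. At 23-29 nt the share with U at position 1 was 72.5%, 69.4% and 61.1%, with A at position 10 it was 31.2%, 33.0% and 31.2%, and the HeT-A ping-pong share was 64.4%, 63.5% and 66.0%. At 25-27 nt these were 74.7%, 71.7% and 64.9%, then 30.7%, 32.7% and 29.4%, and 53.6%, 64.7% and 62.4%. At 25-27 nt HeT-A had log2 ratios of 0.14 for H95/H90, -0.64 for H111/H90 and 0.78 for H95/H111, 42AB had 0.88 for H95/H90 and 0.23 for H95/H111, and lacZ had 1.77 rpm in H95. At 20-22 nt esi-2.1 had 152, 424 and 89.4 rpm.

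With 1 mismatch the HeT-A ping-pong share was 58.5%, 53.1% and 54.9%, and its log2 ratios were 0.15 for H95/H90, -0.63 for H111/H90 and 0.78 for H95/H111. For H95/H111, 3 families slightly above the median contig came to lie below it, accord at -0.097 and both LTR families of the follicle cell list other than gypsy at -0.090 and -0.10. miR-14 moved to 0.0053 for H95/H90. On the whole contig the HeT-A ping-pong share was 56.6%, 54.2% and 59.1% and the log2 ratios were 0.19, -0.94 and 1.13 in the same order of pairs, while within 250 nt the share was 29.9%, 49.4% and 13.6%.

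Scaling decided several directions. In miRNA rpm HeT-A was at 1.06 for H95/H90, -0.49 for H111/H90 and 1.55 for H95/H111, and 42AB at 1.82, 0.81 and 1.01. lacZ was at 12.3, 20.1 and 6.61 miRNA rpm and esi-2.1 at 96.6, 365 and 71.7 miRNA rpm in H90, H95 and H111. With marker reads out of the total HeT-A was at 0.33, -0.44 and 0.77. Per 24-29 nt read outside the miRNA, 2S rRNA, esi-2.1 and marker classes it was at 0.10, 0.029 and 0.072, which reversed H111/H90. Per read of all 24-29 nt reads it was at 0.10, -0.00089 and 0.10, so H111 and H90 were level. Relative to the median contig it was at -0.043, level with that contig, and at 0.51 and -0.49, both reversed. TART was at 0.22 for H111/H90, also reversed, and 42AB at 0.71, 1.81 and, reversed, -1.02. TMM scaling reversed let-7 for H95/H90 (-0.27), bantam (0.34), miR-318 (0.063), miR-1 (0.25) and miR-125 (0.087) for H111/H90, and miR-989 for H95/H111 (-0.43). In rpm of the whole file let-7 was reversed for H95/H90 (-0.49) and miR-989 for H95/H111 (-0.020).

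With at least 10000 reads, 15 of 159 contigs were 2-fold off the median for H95/H90, 12 of 98 for H111/H90 and 21 of 125 for H95/H111. With at least 1000 reads these were 73 of 471, 59 of 431 and 84 of 464. At the minimum of 10000 reads jockey moved to -0.058 for H111/H90. A pseudocount of 10 moved the I-element to 0.0996 for H111/H90. With reads that had 1 place among the contigs, roo was reversed at 0.61 for H95/H90 and 0.26 for H95/H111. Depth limits lacZ, with 28 to 75 reads per library, and the P-element, Su(Ste)-4 and miR-124, with 0 to 65 reads.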

Other observations

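Of the tests below, those of neighbouring miRNA genes, of muscle and nerve miRNAs, of 1 mismatch for TART and of the 10 most abundant TART sequences were chosen only after the result was seen. Some readings of tests planned earlier were also set after their results: the end-base test of miRNAs named a share of variance and a correlation across miRNAs, which are not independent, and its deciding value was switched to the share after the correlation came out undecided at 0.15 (-0.08 to 0.37). The distinct-sequence test of TART met the mark first set for a few abundant sequences but is given as undecided. The readings of the muscle and nerve, 1 mismatch and lacZ tests were likewise set after their values were known. The strain is a biological difference that the design names, and with 1 library per strain it stays open and untested beside every explanation here.

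H95 had a miRNA profile of its own, with 39 of 73 miRNAs at least 2-fold from H90 and miR-1 at a log2 ratio of -2.17. If bias from the ends of the RNAs were the source, the first 3 and last 3 bases of piRNA-size sequences should explain more of the H95/H90 ratios than of the H111/H90 ratios. They explained 7.04% of the variance against 11.1%, a ratio of 0.631. After correction 33 of the 39 miRNAs were 2-fold apart in the same direction, so the end effects as fitted did not account for most of them. The fitted effects had a standard deviation of 0.742 (log2), against 1.87 for the miRNA ratios before and after correction. The correction could thus remove little, and end bias of another form stays open. The fitted variance itself was 1.85 times larger in H95, and the correction moved miRNAs both ways, from 39 to 36 in H95 and from 16 to 22 in H111. A last base C rather than A gave -1.06 in H95/H90 and -0.0010 in H111/H90. A first base U rather than A gave -0.16 and -0.96. Whether muscle or nerve in the dissected ovaries played a part was not decided: miR-1, at -2.17, is itself part of the pattern, its value would also follow from more muscle in H90, and miR-133 (7 reads against 14) and miR-124 (4 against 1) were too few. Neighbouring miRNA genes differed by a median of 1.36 (log2) and other pairs by 1.67, a ratio of 0.813, which lay between the marks set for this test. Of 33 pairs of genes within 1000 nt, 21 were at least 2-fold apart and 24 had separate counting intervals, with a median difference of 1.42. Many of these pairs share a miRNA or lie in a few loci, such as miR-310 to miR-313, so they are not independent. For H111 against H90 the ratio of medians was 1.08. There 23 of 32 close pairs had separate intervals and 13 were at least 2-fold apart. Separate intervals of most close pairs were thus not particular to H95, as far as 1 library per strain and counting error alone can show. A library made or processed in another way is a further candidate, since H95 alone had the exact 30-nt marker sequence and reads up to 121 nt. H90 and H111 also had other 30-nt reads with the marker site. With 1 library per strain such a difference between libraries cannot be told apart from the strain.

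TART small RNAs in H95 stood at 0.72 relative to the median contig against H90. Correction for the ends left 0.68, so the end effects as fitted accounted for little of the value. Leaving out the 10 most abundant sequences of each contig left 0.72. Those 10 held 14.2% of TART reads in H95 and 26.6% in H90. Leaving them out therefore could not lower the TART ratio in rpm, and the test does not decide on other abundant sequences. With 1 mismatch the ratio was 0.89 against 1.05 in rpm, or 0.56 (77.8%) less the shift of the median contig, so a sequence variant as part of the cause stays open. Counting each distinct sequence once left 0.31, 43.8% of the value, which by the mark set beforehand favours a few abundant sequences. Over 471 contigs this count shrank ratios to 0.583 of their size in general, from which 0.42 would follow, so the test does not decide. A higher TART output or copy number in the H95 strain is a candidate explanation that these data cannot separate from other features of the library.

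lacZ small RNAs occurred in all 3 libraries at 28 to 75 reads. Of the 27 distinct sequences of H111, 2 recurred in another library, 7.41% (0.910 to 24.3). The comparison cannot decide on carry-over between libraries, since the share to expect from 1 pool was not computed for its setting. In a smaller setting, 28 reads drawn from the 75 of H90 shared 14.2% of their sequences with the other reads of H90 (4 to 23.1 over 10000 draws). H111 was set against H90 and H95 together, which hold more reads than those left in H90. H90 and H95 shared 2 sequences of 66 each, for which no expected share was computed either. Their antisense shares, 37.3% (26.4 to 49.3) and 6.06% (1.68 to 14.8), lay apart, which argues against a single pool for that pair, while H111 stays open. Of the 24-29 nt lacZ reads, 57.1% in H90, 56.6% in H95 and 52.4% in H111 began with U. Among all 24-29 nt reads outside the marker and other recognised classes these shares were 74.1%, 70.2% and 63.5%. A lacZ transgene in each strain may be the source, which the labels do not state. Neither this nor any other source of lacZ sequence was tested.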
